A study of Drosophila melanogaster with 7 samples.

How the data were processed

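RNA was sequenced from dissected adult Drosophila midguts with the crop, Malpighian tubules and hindgut removed, per the labels' protocols. Flies were raised at 18 °C and shifted to 29 °C for 7 days, which switches on a temperature-sensitive Gal4 driver under escargot (esg) control. Libraries were made from total RNA with the Illumina TruSeq RNA kit, and the series text names the Illumina GAIIx. The 7 libraries form 3 groups: control (driver crossed to w1118, n = 3), Shn-RNAi (n = 2) and Shn-RNAi puc (Shn-RNAi in flies heterozygous for the puckered allele E69, n = 2). The columns of the count table name the group and not the sample, so columns were matched to groups only and are called libraries. The labels do not say whether libraries came from separate animals or pools, so every p-value measures only the spread between these libraries.

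The deposited values were whole-number counts per gene, not scaled to a common total. The submitters' processing notes name Salmon 1.0.0, DESeq2 and the genome build BDGP6. The role of each tool is not given in the sources used here, nor is the rounding of any estimated counts or the use of strand. The table held 10902 genes, and no gene had a total count under 5 over the 7 libraries. Total counts ran from 11552527 to 18490676 per library. Intervals and the floor of 3 counts used for groups at 0 cover counting error only.

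Gene symbols were matched to the Ensembl 115 annotation of BDGP6.54, in which 10884 of the 10902 symbols (99.83%) were found, 840 of them through an older name. Positions are from that annotation. The deposited counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with filterByExpr by group, which left 9076 genes and took out 1826; the tested genes held at least 99.77% of the counts of each library. Libraries were scaled with TMM, and levels are TMM-scaled CPM with the SD over the libraries of a group. One edgeR quasi-likelihood model held all 7 libraries and 3 groups, with 4 residual degrees of freedom and a common biological coefficient of variation of 21.6%. The 3 contrasts were Shn-RNAi against control, Shn-RNAi puc against control and Shn-RNAi puc against Shn-RNAi. P-values were two-sided and adjusted by Benjamini and Hochberg over the 9076 genes, and a gene was called at an adjusted p under 0.05. Every adjusted p given for a gene is from this edgeR test unless another tool is named. The SE of a log2 change is its size divided by the square root of the edgeR F statistic, and is approximate.

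The comparisons, tests, gene lists, naming rule and most alternatives were chosen before the data were examined. Named genes were, per contrast, the 8 called genes with the largest rise and the 8 with the largest fall among those with at least 5 CPM in the higher group and no overlap between libraries; 18 genes named in every contrast; and up to 4 members of each list with the smallest p. Members of a list with 5 or fewer calls in a direction were also named, chosen after their values were seen. The 32 lists were the BMP, JNK (pathway and targets), JAK-STAT, EGFR, Notch, Wingless and Hippo pathways; intestinal progenitor, enteroendocrine and enterocyte markers; digestive enzymes; regional transcription factors; visceral muscle, tracheal, Malpighian tubule, fat body, hemocyte, germline, and female and male markers; cell cycle, antimicrobial and IMD, oxidative stress and detoxification, heat shock and unfolded protein, and matrix, adhesion and invasion genes; tumour-secreted factors; glycolysis; lipid handling; cytosolic ribosomal proteins; nuclear-encoded oxidative phosphorylation genes; V-ATPase subunits; ribosome biogenesis; and reference housekeeping genes. Some genes sit in more than 1 list: upd2 and upd3 (JAK-STAT, tumour-secreted), Mmp1 (JNK, matrix, tumour-secreted), cher (JNK, matrix), Col4a1 and vkg (hemocyte, matrix), Dl, N, Egfr, stg, egr, Ilp6, Ilp8, Yp1, Yp2, Yp3, fit and Gapdh1.

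Lists were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over the 32 lists, which all had at least 5 tested members. Each list was also tested with a correlation estimated per list and with fry, a rotation test of whether a list's genes move one way. Counts of called members are given over all genes tested and adjusted over the list alone. A fold against a group at 0 was computed against 3 counts over that group and is a lower bound; with 1 to 3 counts the ratio is given with its 95% counting interval. Near-identical genes, among them the lysozymes LysB, LysC, LysD, LysE and LysS, the Hsp70 genes, Cyp12d1-d and Cyp12d1-p, PGRP-SC1a and PGRP-SC1b, and Amy-p and Amy-d, may share reads, so their separate values are uncertain. Reads from overlapping or antisense genes could not be told apart.

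The alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, the 50 most abundant genes left out, no low-count filter, a filter of 1 CPM in 2 libraries, a fit of only the 2 groups compared, a least fold change of 2, and each of the 7 libraries left out in turn. After the data were seen, 3 more were added: a per-library trend on transcript length taken out through offsets (longest annotated transcript, lowess span 0.3), control library 2 and Shn-RNAi library 2 left out together, and a block for the replicate number in the column names. A group left with 1 library is assumed to vary like the other groups. No contrast had 3 libraries in both groups, so other splits of the samples were not counted. Genes called the same way against the shared controls were also counted in 40 simulations with unchanged groups.

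The edgeR test was checked on simulated counts for the 9076 genes with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 30% and 78% of them for Shn-RNAi against control (4 false among 112 calls), 35% and 95% for Shn-RNAi puc against control (7 of 137), and 23% and 89% for Shn-RNAi puc against Shn-RNAi (12 of 124). A simulated list with shifted members was recovered in all 3 contrasts, with 0 other lists called. Genes were simulated independently of each other, so this does not check false calls among lists of correlated genes. GC content was not analysed here.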

Results

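Transcript levels were measured by RNA sequencing in 7 libraries of adult Drosophila midgut, taken 7 days after flies were moved from 18 to 29 °C. The driver, esgts, is a temperature-sensitive system active in the intestinal stem cells and their immediate daughters. The control group (driver and w1118) had 3 libraries. The group labelled Shn-RNAi, in which the driver expresses RNA interference against schnurri (shn), a nuclear cofactor of BMP signalling, had 2. The group labelled Shn-RNAi puc, described as also carrying 1 mutant copy of puckered (puc), a phosphatase that restrains JNK, had 2. The series title orders the 3 groups as control, tumor and severe tumor. Total counts were 15885233, 18490676 and 14665728 in the control libraries, 15716078 and 14673142 in the libraries labelled Shn-RNAi, and 14688825 and 11552527 in the libraries labelled Shn-RNAi puc. Between 10048 and 10601 of the 10902 genes had a count in each library. The 10 most abundant genes held 28.3% to 31.1% of the control counts, 21.9% and 26.3% of the Shn-RNAi counts, and 22.3% and 21.8% of the Shn-RNAi puc counts. The first principal component held 52.6% of the variance and set the 3 control libraries apart from the other 4. The second held 14.7% and set Shn-RNAi library 2 apart from the other 6.

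The targeted gene shn (2R 11159086 to 11217394, plus strand) was not lower in either RNAi group. Its level was 42.5, 47.4 and 42.4 CPM in the control libraries, 68.6 and 54.1 CPM in the libraries labelled Shn-RNAi, and 66.5 and 69.7 CPM in the libraries labelled Shn-RNAi puc. The difference from control was 0.48 on the log2 scale (SE 0.15, edgeR adjusted p = 0.091) in the libraries labelled Shn-RNAi and 0.63 (SE 0.15, edgeR adjusted p = 0.031) in those labelled Shn-RNAi puc. The second call was kept in 2 of the 7 refits that each left out 1 library (highest adjusted p = 0.19, without Shn-RNAi puc library 2) and not with the transcript-length trend taken out (adjusted p = 0.063). The RNAi acts only in cells where the driver is active, so whole-midgut RNA need not show a fall. The shn counts therefore do not check the RNAi labels, and every direction below is that of libraries named by their label. Transcripts of puc (3R 8105332 to 8122294, plus strand) stood at 72.3, 70.2 and 82.2 CPM in control, 93.5 and 101 CPM in the libraries labelled Shn-RNAi, and 86.5 and 88.3 CPM in those labelled Shn-RNAi puc. The log2 difference in puc was 0.38 (SE 0.14, edgeR adjusted p = 0.13) and 0.22 (SE 0.14, adjusted p = 0.34) against control, and -0.16 (SE 0.16, adjusted p = 0.92) between the RNAi groups. Transcript counts do not show whether the mutant copy was present.

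**Figure D1:**
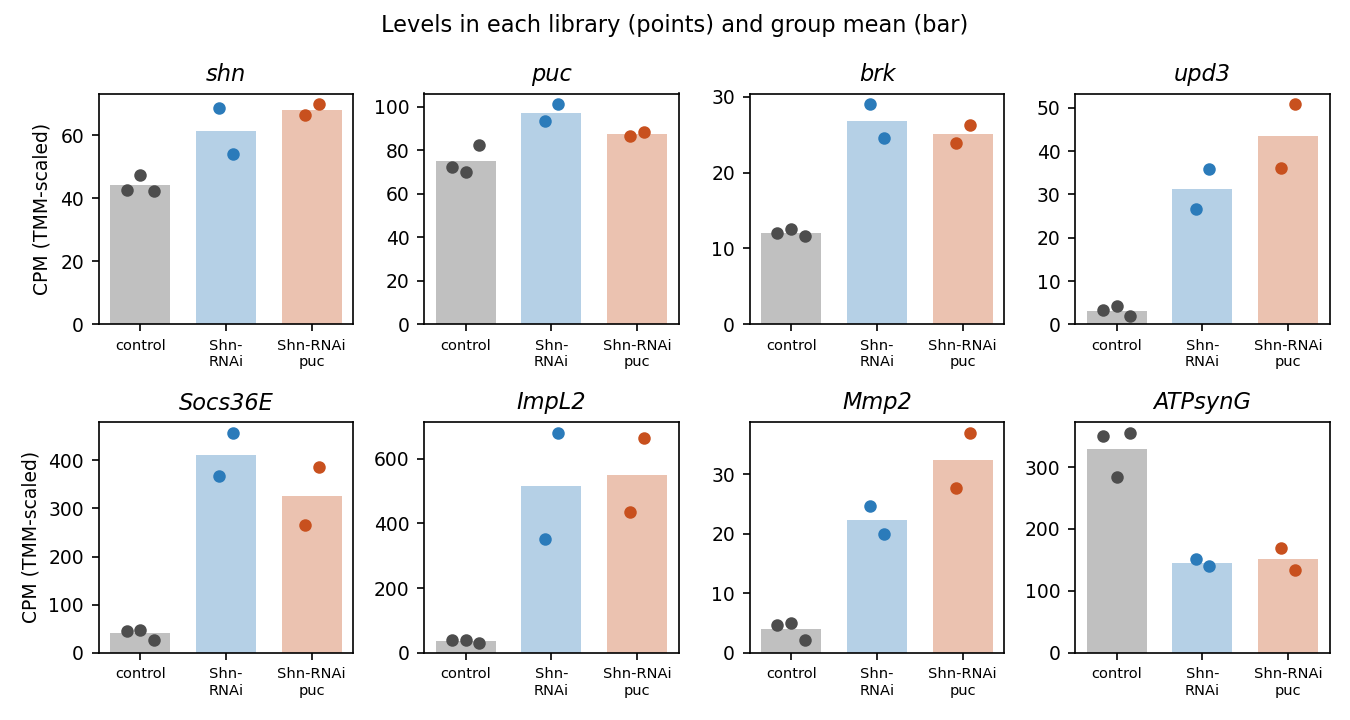
TMM-scaled CPM (linear axis) of selected genes in each of the 7 libraries, with points for libraries and bars for group means. The shn points of both RNAi groups, 54.1 to 69.7 CPM, lie above the 3 control points, 42.4 to 47.4 CPM.

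The first comparison asked which transcripts differed between control midguts and midguts of the group called tumor. Because control flies came from a cross to w1118, differences in strain background cannot be told apart from the RNAi in either comparison with control. The secreted signals of the JAK-STAT pathway stood far higher in the libraries labelled Shn-RNAi (n = 2) than in control (n = 3): upd1 at 17.4 ± 5.46 against 0.0184 ± 0.0319 CPM, upd3 at 31.3 ± 6.47 against 3.11 ± 1.22 CPM, and their feedback inhibitor Socs36E at 412 ± 63.6 against 40.2 ± 11.1 CPM (mean ± SD). ImpL2, a secreted protein that binds insulin-like peptides, was 14.3-fold higher (516 ± 232 against 36.1 ± 6.42 CPM). Cell cycle (6 of 62 genes passed), matrix (12 of 31), EGFR (6 of 19) and JNK lists (6 of 19) were called higher by camera with its preset correlation, and none of them with an estimated correlation (adjusted p = 0.52, 0.51, 0.32 and 0.51). Nuclear genes of oxidative phosphorylation had a median log2 change of -0.81 over 65 genes, 28 of them lower (adjusted p = 0.51 with an estimated correlation).

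The largest rises included Cyp12d1-d, a cytochrome P450, with 0 counts in control and 82.9 ± 2.94 CPM in the libraries labelled Shn-RNAi, at least 1240-fold higher than 3 counts over the control group allow. TotA, a Turandot stress peptide, had 0 counts in control and was at least 331-fold higher (23.6 ± 14.4 CPM). The chitin-binding gene obst-I was 1710-fold higher (counting interval 306 to 67500), upd1 754-fold (135 to 29800) and CG43074 231-fold (40.9 to 9180). TotC (log2 change 11.45, SE 0.98), CG32302 (8.28, SE 0.65) and the lysozyme LysC (6.59, SE 0.38) completed the 8 largest, with edgeR adjusted p from 0.00014 to 0.0043. The log2 change of TotC was 12.35 without control library 2, 12.20 without Shn-RNAi library 1 and 9.77 without Shn-RNAi library 2, and that of LysC 5.90 without Shn-RNAi library 2. Genes with 0 or 1 control counts moved too, and their fitted log2 changes depend on the model. That of obst-I went from 10.34 to 9.73 without control library 2 and 12.27 without control library 3, that of upd1 from 9.15 to 10.99 without control library 2, that of CG43074 from 7.49 to 9.32 without control library 2 and 6.66 without Shn-RNAi library 2, and that of TotA to 10.69 without Shn-RNAi library 2. TotA, TotC and LysC were very uneven between the libraries labelled Shn-RNAi (TotC 642 ± 624 CPM), and the reads of LysC and Cyp12d1-d may be shared with near-identical genes. The largest falls were in mwh, a gene of wing-hair polarity (63.3 ± 5.81 to 2.12 ± 0.407 CPM, log2 -4.88, SE 0.25), CG32379 (-4.58, SE 0.22), CG17192 (-4.31, SE 0.42), CG6295 (-3.28, SE 0.22), the cytochrome P450 Cyp4d1 (-3.15, SE 0.43), CG5157 (-3.09, SE 0.25), CG32751 (-3.03, SE 0.26) and AANATL4 (-2.78, SE 0.39). Their edgeR adjusted p ran from 0.00014 to 0.006. Without Shn-RNAi library 1 the log2 change was -5.07 for CG17192 and -4.01 for Cyp4d1.

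In all, 550 of 9076 genes were higher and 323 lower in the libraries labelled Shn-RNAi (edgeR adjusted p under 0.05), 406 and 156 of them by at least 2-fold. The counts were 221 and 64 without control library 1 and 278 and 92 without control library 3. They were 300 and 154 without Shn-RNAi library 2, 312 and 158 without Shn-RNAi puc library 1, and 314 and 159 without Shn-RNAi puc library 2. Long transcripts stood higher in some libraries than in others. With genes in 4 classes of equal size by transcript length, the median of the longest class minus that of the shortest was -0.32, -0.01 and -0.41 on the log2 scale in the control libraries. It was 0.61 and -0.27 in those labelled Shn-RNAi, and 0.08 and 0.33 in those labelled Shn-RNAi puc. Of the called genes in the longest class, 212 were higher and 12 lower, against 114 and 129 in the shortest. With that trend taken out, 714 genes were higher and 493 lower, and 786 of the 873 calls were kept. DESeq2 called 595 lower.

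With a correlation estimated from the data none of the 32 lists was called in this comparison (lowest adjusted p = 0.32). Fry called 10 lists. Its adjusted p was 0.011 for JAK-STAT, EGFR and tumour-secreted, 0.016 for JNK, and 0.034 for BMP, Wingless, matrix and muscle lists. Germline (0.011) and enterocyte (0.046) lists, not called by camera, were the others. Oxidative phosphorylation (0.052), cell cycle, ribosomal and V-ATPase lists (0.057 each) and progenitor markers (0.11) were not called by fry. In the JAK-STAT list 7 of 12 members were higher and 0 lower (8 adjusted over the list alone, camera adjusted p = 5.2e-12, adjusted p = 0.32 with an estimated correlation). They included upd1, upd2 and upd3, the receptor dome (log2 change 1.59, SE 0.22, edgeR adjusted p = 0.0054) and Socs36E (3.36, SE 0.29, adjusted p = 0.001). Of the tumour-secreted factors 5 of 13 were higher and 0 lower (8 and 1 adjusted over the list alone, camera adjusted p = 2.1e-07, adjusted p = 0.32 with an estimated correlation): ImpL2 (3.84, SE 0.33), upd3 (3.30, SE 0.31), upd2 (3.31, SE 0.72), the Toll ligand spz (2.27, SE 0.28) and the PDGF- and VEGF-like ligand Pvf2 (2.09, SE 0.38). The EGFR list had 6 of 19 higher and 0 lower (9 and 1 adjusted over the list alone, camera adjusted p = 1.6e-06, adjusted p = 0.32 with an estimated correlation), among them the nuclear regulator edl (2.20, SE 0.22), the ERK phosphatase Mkp3 (1.39, SE 0.17), the neuregulin-like ligand vn (1.99, SE 0.30) and the ligand-processing protease rho (2.82, SE 0.42). Their edgeR adjusted p ran from 0.0016 to 0.0078. With 1 library left out at a time, upd2 kept its call in 2 of 7 refits (highest adjusted p = 0.12, without Shn-RNAi library 1). Its log2 change was 2.39 without that library and 4.08 without control library 2. Pvf2 kept its call in 2 refits (highest 0.076, without Shn-RNAi library 2).

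The JNK list had 6 of 19 members higher and 0 lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.00031, adjusted p = 0.51 with an estimated correlation). The smallest p were those of cher, a filamin (2.64, SE 0.23, edgeR adjusted p = 0.001), Gadd45 (1.06, SE 0.15, adjusted p = 0.006), the kinase msn (1.02, SE 0.16, adjusted p = 0.0093) and the TNF receptor grnd (1.70, SE 0.33, adjusted p = 0.019). The Fos protein kay was also higher (1.02, SE 0.20, adjusted p = 0.019). The BMP list, to which shn itself belongs, had 5 of 17 higher and 0 lower (8 adjusted over the list alone, camera adjusted p = 0.00024, adjusted p = 0.51 with an estimated correlation). These were the BMP-binding protein cv-2 (1.73, SE 0.16, edgeR adjusted p = 0.0013), the repressor brk (1.15, SE 0.14, adjusted p = 0.003), the signal transducer Mad (1.14, SE 0.22, adjusted p = 0.018), the ligand gbb (1.29, SE 0.25, adjusted p = 0.02) and magu (0.86, adjusted p = 0.022). Members were counted by transcript level alone, and a higher level of a repressor such as brk does not mean more BMP signalling. The Wingless list had 4 of 15 higher (4 adjusted over the list alone, camera adjusted p = 0.0049, adjusted p = 0.51 with an estimated correlation): the ligands wg (2.93), Wnt5 (1.60) and Wnt4 (1.38), and Apc (1.58). That list was not called without Shn-RNAi library 1 (adjusted p = 0.25) or with the length trend taken out (0.17). Of the genes in these lists, kay was called in 4 of the 7 refits that left out 1 library, gbb and magu in 3, Mad and grnd in 2, msn and wg in 6, Wnt5 in 4 and Wnt4 in 1. Their highest adjusted p, between 0.053 and 0.11, came without control library 1, or without Shn-RNAi library 2 for grnd, wg and Wnt5.

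Matrix, adhesion and invasion genes had 12 of 31 members higher and 0 lower (16 adjusted over the list alone, camera adjusted p = 4.3e-08, adjusted p = 0.51 with an estimated correlation). Beside cher they included the integrin subunits ItgaPS4 (2.35, SE 0.29, edgeR adjusted p = 0.0033) and mys (1.52, SE 0.23, adjusted p = 0.0082) and the matrix metalloproteinase Mmp2 (2.48, SE 0.31, adjusted p = 0.0036). Cell cycle genes had 6 of 62 higher and 0 lower (6 adjusted over the list alone), with a median log2 change of 0.74 over the list (camera adjusted p = 8.5e-07, adjusted p = 0.52 with an estimated correlation). The 4 with the smallest p were the centrosomal gene tacc (0.81), the replication factor Psf1 (1.58), the anillin gene scra (1.34) and Top2, a DNA topoisomerase (0.69). Intestinal progenitor markers had 2 of 16 higher, the transcription factor peb (0.79) and hdc (1.00), and 0 lower (7 adjusted over the list alone, camera adjusted p = 0.0049, adjusted p = 0.62 with an estimated correlation). This list was not called without Shn-RNAi library 1 (adjusted p = 0.16) or with the length trend taken out (0.086). The stem-cell genes esg (0.07, SE 0.21, edgeR adjusted p = 0.88) and Dl (0.59, SE 0.40, adjusted p = 0.4) did not pass. Leaving out 1 library at a time kept tacc in 6 of 7 refits, Psf1 in 4, peb in 3, and scra, Top2 and hdc in 1 each. The highest adjusted p, 0.053 to 0.15, came without control library 1, or without Shn-RNAi puc library 1 for Psf1 and Shn-RNAi library 1 for hdc. The log2 change of Psf1 was 0.99 without Shn-RNAi library 2. With the length trend taken out, tacc (adjusted p = 0.062), peb (0.087) and hdc (0.059) were not called.

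The oxidative phosphorylation list had 28 of 65 members lower and 0 higher (60 lower adjusted over the list alone, camera adjusted p = 3.2e-22, adjusted p = 0.51 with an estimated correlation). The ATP synthase genes ATPsynG (329 ± 39.7 to 146 ± 7.95 CPM, log2 -1.17, SE 0.19, edgeR adjusted p = 0.01) and ATPsynO (-1.08, SE 0.21, adjusted p = 0.019) and the complex I genes ND-20 (-0.86, SE 0.17, adjusted p = 0.02) and ND-39 (-0.93, SE 0.19, adjusted p = 0.024) had the smallest p. Each was called in 3 to 5 of the 7 refits that left out 1 library (highest adjusted p = 0.094, for ND-39 without control library 1). With the length trend taken out the list median was -0.67 and the list was still called. The visceral muscle list was lower (camera adjusted p = 0.0077, adjusted p = 0.51 with an estimated correlation), with 4 of 21 members lower and 1 higher (7 and 1 adjusted over the list alone). The troponin TpnC47D (-1.27, SE 0.16, edgeR adjusted p = 0.0038), the actins Act87E (-1.20, SE 0.18, adjusted p = 0.0071) and Act57B (-0.90, SE 0.20, adjusted p = 0.032) and Mlc2 (-0.68, adjusted p = 0.039) were lower, and Zasp52 was higher (0.99, SE 0.16, adjusted p = 0.0096). Cytosolic ribosomal proteins had 0 of 83 called by edgeR, in either direction or adjusted over the list alone, with a median of -0.38 (camera adjusted p = 5.8e-09, adjusted p = 0.62 with an estimated correlation). V-ATPase subunits had 1 of 20 lower, VhaAC39-2 (-1.81, SE 0.29), and 3 adjusted over the list alone, with a median of -0.46 (camera adjusted p = 0.00024, adjusted p = 0.52 with an estimated correlation). Leaving out 1 library kept Zasp52 in 6 of 7 refits, Act57B in 2 and Mlc2 in 0 (highest adjusted p = 0.17, without control library 1), and with the length trend taken out Zasp52 had an adjusted p of 0.053.

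The other 19 lists were not called, with camera adjusted p from 0.077 to 0.93. Digestive enzymes moved both ways, with 11 of 53 members higher and 7 lower (12 and 21 adjusted over the list alone; median -0.27, mean 0.22, camera adjusted p = 0.43, downward). The lysozymes LysD (6.38, SE 0.55), LysS (5.87, SE 0.53), LysB (5.72, SE 0.59) and LysE (2.40, SE 0.29) led the rise. LysD stood at 6170 CPM in Shn-RNAi library 1 and 24100 CPM in library 2, and the log2 changes of LysD, LysS and LysB were 7.06, 6.54 and 6.44 without the first and 5.10, 4.63 and 4.23 without the second. Oxidative stress and detoxification genes had 5 of 37 higher and 6 lower (6 and 9 adjusted over the list alone; median 0, mean 0.10, camera adjusted p = 0.63, downward). The cytochrome P450 genes Cyp6a2 (2.04) and Cyp6w1 (4.29; 3.39 without Shn-RNAi library 1) and the glutathione transferases GstE5 (1.84), GstE1 (0.97) and GstD3 (1.01) rose, and Gclm (-1.12), for glutathione synthesis, was among those that fell. Antimicrobial and IMD genes had 2 of 22 higher (3 adjusted over the list alone, camera adjusted p = 0.32), the Drosomycin-like genes Drsl3 (5.41; 4.46 without Shn-RNAi library 2) and Drsl2 (5.99; 6.79 and 4.05 without Shn-RNAi library 1 and 2). Enterocyte markers had 4 of 17 higher (5 adjusted over the list alone, camera adjusted p = 0.077): the junction genes mesh (0.90), cora (0.77) and Nrg (1.44) and the transcription factor nub (0.93). Heat shock and unfolded protein genes had 1 of 24 higher (1 adjusted over the list alone, camera adjusted p = 0.25), the co-chaperone stv (0.96).

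Enteroendocrine markers had 1 of 22 higher, the peptide hormone CCHa1 (1.60; 0.82 without Shn-RNAi library 2), and 1 lower, nrv3 (-2.25), a sodium pump subunit (4 and 2 adjusted over the list alone, camera adjusted p = 0.59). In 9 more lists 1 or 2 members passed. The Notch list had fng (1.53; 1 of 13, 3 adjusted over the list alone, camera adjusted p = 0.077) and the Hippo list kibra (0.65; 1 of 14, 2; 0.27). Regional transcription factors had drm (1.26; 1 of 17, 1; 0.93, downward against a mean of 0.04), and fat body markers Tep4 (1.42) and Lsp1gamma (1.77; 2 of 10, 2 and 1; 0.82, upward against a median of -0.15). Glycolysis had Ldh, higher (1.30; 1 of 16, 2 and 7; 0.077, downward, with a median of -0.32 and 13 members negative). Lipid handling had AcCoAS (1.23) and Hsl (0.66; 2 of 20, 2 and 1; 0.75). The germline list had piwi (1.99; 1 of 5, 1; 0.2), tubule markers the water channel Drip, lower (-1.36; 1 of 14, 1; 0.44), and ribosome biogenesis Rrp1 (0.99; 1 of 28, 0; 0.32), a DNA repair endonuclease in this species. Tracheal (9 tested, camera adjusted p = 0.59), hemocyte (10; 0.43), female and male (8; 0.11) and housekeeping genes (10; 0.25) had 0 called by edgeR over all genes. Adjusted over the list alone the first 3 had 0 and the housekeeping genes 3 lower. Control was uneven in some tracheal, fat body and hemocyte genes. Control library 2 stood above libraries 1 and 3 in verm (22 against 1.58 and 2.63 CPM) and apolpp (60.9 against 27.5 and 15.3 CPM). The same held for PPO2 (2.27 against 0.215 and 0.956 CPM). With 1 library left out, fng, GstE1, Gclm and stv were called in 2 of 7 refits, nub, cora, CCHa1 and Rrp1 in 1, and mesh, Nrg and Hsl in 4. Among the others, Ldh, AcCoAS and Lsp1gamma were called in 5, nrv3 and Tep4 in 6, and kibra, piwi and GstD3 in 0 (highest adjusted p, 0.053 to 0.16, mostly without control library 1 or Shn-RNAi library 2). The calls of kibra (adjusted p = 0.089) and mesh (0.05) were lost with the length trend taken out. Of the genes named in every comparison, dpp (0.59, SE 0.20, edgeR adjusted p = 0.1), Dad, Krn, spi, Mmp1, stg, pros and Tk did not pass, with log2 changes from 0.27 to 0.66 and adjusted p from 0.1 to 0.82.

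Of the 90 called genes named for this comparison, 51 kept their call without control library 1, 78 without control library 2, 61 without control library 3, 70 and 56 without Shn-RNAi library 1 and 2, and 69 without either library labelled Shn-RNAi puc. In every refit 47 kept it. Both libraries labelled Shn-RNAi also differed from each other more than the other replicate pairs, with a chi-square per gene of 187 against 20.5 to 49.7.

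**Figure D2:**
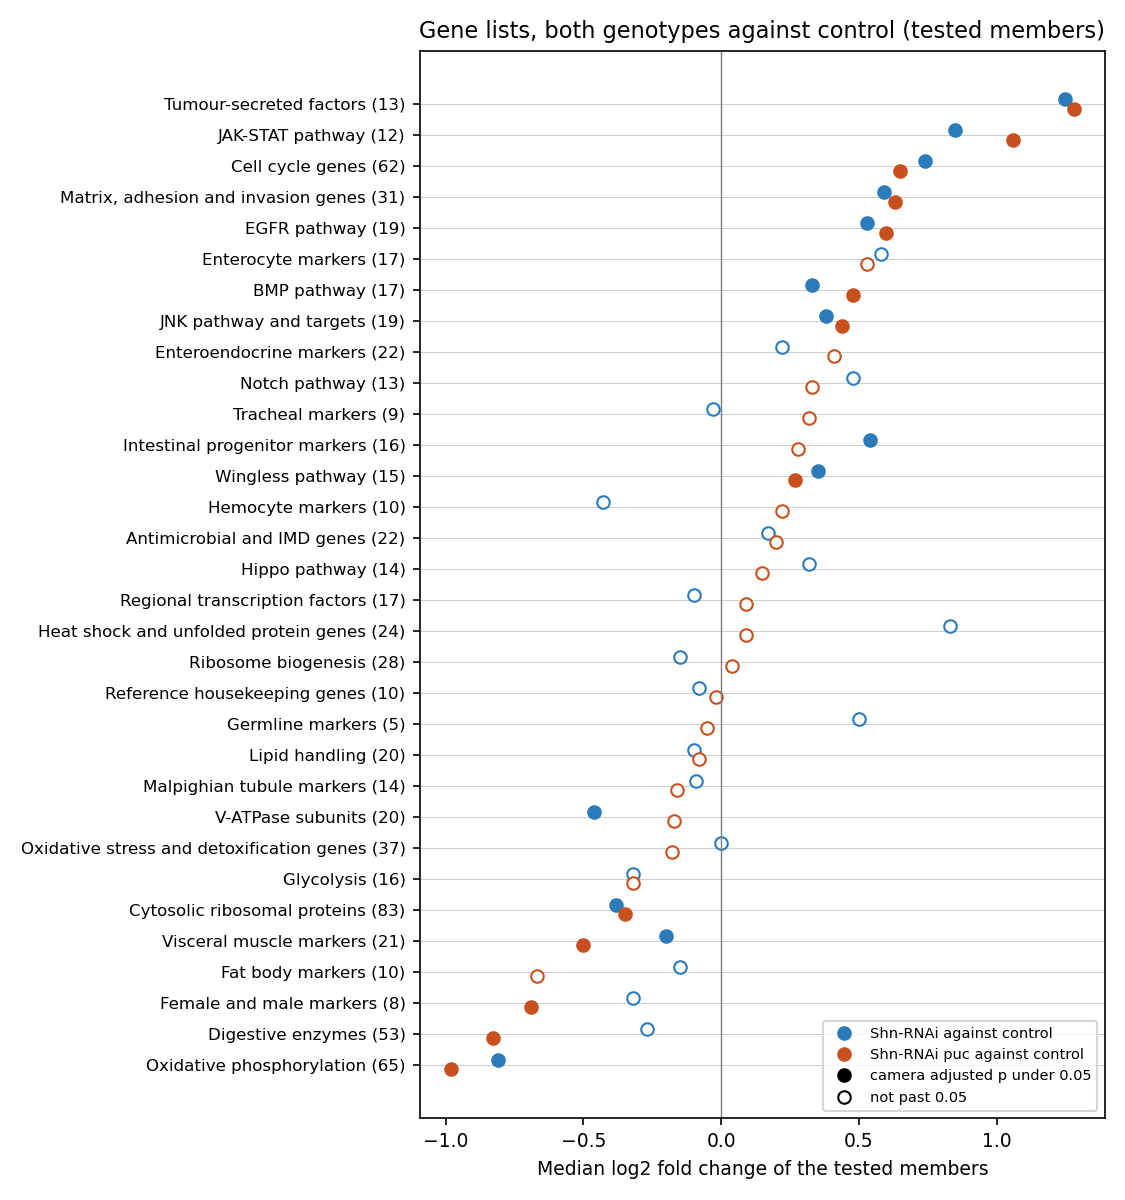
Median log2 fold change of the tested members of each of the 32 gene lists, in both comparisons with control. Filled points mark lists with a camera adjusted p under 0.05 at the preset correlation, and open points mark the others. The oxidative phosphorylation medians lie at -0.81 and -0.98 and the JAK-STAT medians at 0.85 and 1.06.

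The second comparison asked the same of the group called severe tumor. In the libraries labelled Shn-RNAi puc (n = 2) against control (n = 3), the cytokine genes upd1 (15.4 ± 1.44 against 0.0184 ± 0.0319 CPM), upd3 (43.5 ± 10.4 against 3.11 ± 1.22 CPM) and upd2 (5.45 ± 3.58 against 0.248 ± 0.168 CPM) were higher, and so was ImpL2, 15.2-fold (549 ± 162 against 36.1 ± 6.42 CPM). Digestive enzymes went both ways, 17 of 53 lower and 8 higher, with a median log2 change of -0.83. That list was called lower by camera with its preset correlation, but not with an estimated one (adjusted p = 0.6), with the length trend taken out (0.11) or without Shn-RNAi library 2 (0.25). Oxidative phosphorylation genes had a median of -0.98, with 55 of 65 lower (adjusted p = 0.46 with an estimated correlation).

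The largest rises were in Cyp12d1-d (60.1 ± 10.3 CPM, at least 898-fold above the control level that 0 counts allow), CG32581 (20.2 ± 2.39 CPM, at least 299-fold) and CG42704 (15.2 ± 5.08 CPM, at least 228-fold), which all had 0 counts in control. Next came upd1, 687-fold higher (counting interval 123 to 27200), obst-I, 572-fold (102 to 22600), LysC (log2 7.82, SE 0.39), TotC (7.11, SE 0.93; 8.0 without control library 2) and CG9360 (6.90, SE 0.44; 6.29 without Shn-RNAi puc library 1). The fitted log2 change of upd1 went from 8.98 to 10.80 without control library 2. That of obst-I went from 8.68 to 8.07 without control library 2, 10.60 without control library 3 and 7.94 without Shn-RNAi puc library 1. Their edgeR adjusted p ran from 0.00022 to 0.0037. The largest falls were in CG17192 (-4.65, SE 0.43), CG13160 (-3.67, SE 0.40), PGRP-SC1a, a peptidoglycan amidase (-3.65, SE 0.82), CG32379 (-3.56, SE 0.20), CG30047 (-3.50, SE 0.55), CG5157 (-3.41, SE 0.25), CG32751 (-3.39, SE 0.27) and the protease Jon25Bi (5060 ± 1310 to 503 ± 41.6 CPM, -3.33, SE 0.30), with edgeR adjusted p from 0.00024 to 0.024. Leaving out 1 library kept PGRP-SC1a in 4 of 7 refits (highest adjusted p = 0.2) and CG30047 in 5 (0.094), both highest without Shn-RNAi puc library 2.

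In all, 795 of 9076 genes were higher and 567 lower in the libraries labelled Shn-RNAi puc (edgeR adjusted p under 0.05), 474 and 296 of them by at least 2-fold. The counts were 299 and 141 without control library 1 and 392 and 196 without control library 3. They were 197 and 92 without Shn-RNAi puc library 1, and 139 and 33 without Shn-RNAi puc library 2, and 1194 and 1012 when only these 2 groups were fitted. Of the called genes in the longest class, 277 were higher and 27 lower, against 122 and 275 in the shortest. With the length trend taken out, 998 were higher and 754 lower, and 1220 of the 1362 calls were kept.

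With a correlation estimated from the data none of the 32 lists was called here either (lowest adjusted p = 0.38). Fry called 9 lists: JAK-STAT, EGFR, JNK, tumour-secreted and muscle (adjusted p = 0.012), BMP and matrix (0.026), oxidative phosphorylation (0.036) and enterocyte (0.046). It did not call the Wingless (0.053), female and male (0.053), cell cycle (0.09), ribosomal (0.1) or digestive lists (0.14). The JAK-STAT list had 8 of 12 higher (8 adjusted over the list alone, camera adjusted p = 1e-11, adjusted p = 0.38 with an estimated correlation). Its member dome rose by a log2 change of 1.67 (SE 0.22, edgeR adjusted p = 0.0037) and Socs36E by 3.02 (SE 0.28, adjusted p = 0.0011). Tumour-secreted factors had 7 of 13 higher (8 adjusted over the list alone, camera adjusted p = 3e-07, adjusted p = 0.41 with an estimated correlation), including upd3 (3.78, SE 0.31), ImpL2 (3.93, SE 0.33), spz (2.30, SE 0.28), upd2 (4.33, SE 0.69) and Mmp1. The EGFR list had 7 of 19 higher (12 adjusted over the list alone, camera adjusted p = 6e-06, adjusted p = 0.41 with an estimated correlation), led by edl (2.46, SE 0.22), Mkp3 (1.80, SE 0.16), rho (3.33, SE 0.42; 2.66 without Shn-RNAi puc library 2) and the transcription factor Ets21C (2.35, SE 0.31), with vn at 1.99 (SE 0.30). The JNK list had 9 of 19 higher (10 adjusted over the list alone, camera adjusted p = 0.00014, adjusted p = 0.41 with an estimated correlation), with cher (2.42, SE 0.23), Gadd45 (1.23, SE 0.15), grnd (2.08, SE 0.33; 1.44 without Shn-RNAi puc library 2), msn (0.82, SE 0.16), kay (0.94, SE 0.20) and Mmp1 (0.71, SE 0.20). The BMP list had 7 of 17 higher (8 adjusted over the list alone, camera adjusted p = 0.00014, adjusted p = 0.46 with an estimated correlation), including cv-2 (1.92, SE 0.16), brk (1.06, SE 0.14), magu (1.04, SE 0.17), Mad (1.12, SE 0.22), dpp (0.90, SE 0.20, edgeR adjusted p = 0.024) and shn. The Wingless list had 4 of 15 higher (4 adjusted over the list alone, camera adjusted p = 0.042, adjusted p = 0.6 with an estimated correlation): Apc (1.56), Wnt5 (1.67), wg (1.93) and Wnt4 (1.24). It was not called in 5 of the 7 refits that left out 1 library (highest adjusted p = 0.12) or with the length trend taken out (0.33), and dpp lost its call with that trend out (0.087).

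Of the genes in those lists, dome, Ets21C, grnd, Apc, Wnt5 and upd2 were called in 6 of the 7 refits that left out 1 library, vn and magu in 5, Mad in 4, dpp, kay, msn, wg and Wnt4 in 3, and Mmp1 in 2. The highest adjusted p, from 0.054 for dome to 0.22 for Mmp1, came without Shn-RNAi puc library 2, or without Shn-RNAi puc library 1 for wg and Wnt4. The log2 change of upd2 was 5.07 without control library 2 and 3.46 without Shn-RNAi puc library 2.

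Matrix, adhesion and invasion genes had 13 of 31 higher and 0 lower (16 adjusted over the list alone, camera adjusted p = 2.2e-08, adjusted p = 0.41 with an estimated correlation), with cher, Mmp2 (3.02, SE 0.31), ItgaPS4 (2.48, SE 0.29) and the integrin beta subunit Itgbn (1.12, SE 0.16) at edgeR adjusted p from 0.0011 to 0.0055. Cell cycle genes had 4 of 62 higher (1 adjusted over the list alone; median 0.65, camera adjusted p = 0.00013, adjusted p = 0.79 with an estimated correlation): tacc (1.08), the kinetochore gene Ndc80 (1.5), Top2 (0.61) and scra (1.02). Progenitor markers had 1 of 16 higher, the transcription factor sna (3.18, SE 0.70; 4.31 without control library 2), with 1 adjusted over the list alone, and the list was not called (camera adjusted p = 0.18). The levels of esg (0.11, SE 0.21, edgeR adjusted p = 0.77) and Dl (0.37, SE 0.41, adjusted p = 0.6) did not pass. Leaving out 1 library kept Itgbn in 5 of 7 refits, Top2, scra and sna in 2, and Ndc80 in 1 (highest adjusted p = 0.33), each highest without Shn-RNAi puc library 2.

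The oxidative phosphorylation list had 55 of 65 members lower and 0 higher (64 adjusted over the list alone, camera adjusted p = 2.7e-26, adjusted p = 0.46 with an estimated correlation), with ATPsynG (-1.13, SE 0.19), the cytochrome oxidase genes COX5B (-1.04, SE 0.19) and COX7C (-1.10, SE 0.20) and the complex I gene ND-18 (-1.11, SE 0.21) at edgeR adjusted p from 0.0091 to 0.014. With the length trend taken out its median was -0.76. Visceral muscle genes had 10 of 21 lower and 1 higher (10 and 2 adjusted over the list alone, camera adjusted p = 0.00014, adjusted p = 0.41 with an estimated correlation), with TpnC47D (-2.05, SE 0.17), Act87E (-1.77, SE 0.18) and Act57B (-1.23, SE 0.20) lower and Zasp52 higher (1.43, SE 0.16). Digestive enzymes had 17 of 53 lower and 8 higher (23 and 8 adjusted over the list alone; median -0.83, camera adjusted p = 0.00033, adjusted p = 0.6 with an estimated correlation). Jon25Bi fell by 3.33 on the log2 scale, and LysE (3.67, SE 0.30), LysD (5.55, SE 0.53) and LysS (5.39, SE 0.52) rose. The digestive list was not called without Shn-RNAi library 2 (adjusted p = 0.25) or with the length trend taken out (0.11). Cytosolic ribosomal proteins had 0 of 83 lower and 1 higher, RpS5b (2.25, SE 0.59; 3.22 without control library 2), with 0 adjusted over the list alone, a median of -0.35 and a camera adjusted p of 4.2e-06 (adjusted p = 0.85 with an estimated correlation; 0.26 with the length trend taken out). Female and male markers had 1 of 8 lower, dsx (-0.72, SE 0.16), and 2 adjusted over the list alone (camera adjusted p = 0.037, adjusted p = 0.47 with an estimated correlation), and were not called without control library 2 or Shn-RNAi puc library 1 (highest adjusted p = 0.13). Leaving out 1 library kept ATPsynG and Act57B in 6 of 7 refits, ND-18 in 5, COX5B and COX7C in 4, dsx in 2 and RpS5b in 1, with the highest adjusted p, 0.072 to 0.33, without Shn-RNAi puc library 2.

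The remaining 19 lists were not called (camera adjusted p from 0.073 to 0.98). Their called members, in order of p within a list, were Drsl3 (5.01), PGRP-LA (0.87), Drsl2 (3.50) and the NF-kappaB protein Rel (0.88), higher, and PGRP-SC1a and PGRP-SC1b (-3.12), lower, among antimicrobial genes (4 and 2 of 22). Enteroendocrine markers had CCHa1 (2.17) and the proneural gene sc (1.87) higher and nrv3 (-1.71) and the peptide hormone NPF (-0.90) lower. Enterocyte markers had Nrg (1.97), mesh (1.00), cora (0.90) and nub (0.79) higher and Smvt (-1.22), a vitamin transporter, lower. Tubule markers had ry (1.59), byn (1.25) and Esp (1.11) higher and Oatp58Db (-1.31) and Drip (-0.76) lower. Lipid handling had AcCoAS (1.5), Hsl (0.72), whd (1.79; 0.88 without Shn-RNAi puc library 1), for fatty acid import into mitochondria, and FASN2 (2.53; 3.31 without control library 3) higher, and the lipid droplet gene Lsd-1 (-2.07; -2.86 without Shn-RNAi puc library 1) lower. Oxidative stress and detoxification genes had 5 of 37 higher, Cyp6a2 (2.43), GstE5 (1.43), Irc (0.77), Cyp6w1 (2.57; 1.38 and 3.22 without Shn-RNAi puc library 1 and 2) and GstE1 (0.92), and 8 lower, including Cyp12d1-p (-1.04) and the peroxiredoxin Jafrac1 (-1.08). The Hippo list had kibra (0.61), sd (0.57) and Diap1 (0.65) higher. A single gene passed in the Notch (fng, 1.76), regional (drm, 0.64), fat body (Tep4, 1.62), hemocyte (Hml, 2.61), germline (AGO3, -1.86), glycolysis (Ldh, 1.64) and V-ATPase (VhaAC39-2, -1.80) lists, and stv (0.97) was higher and the chaperone Gp93 (-0.88) lower in the heat shock list. Most glycolysis genes went the other way from Ldh (median -0.32, 12 of 16 members negative). Tracheal, ribosome biogenesis and housekeeping lists had 0 called by edgeR, 0 adjusted over the list alone, and camera adjusted p of 0.98, 0.98 and 0.57. Adjusted over the list alone, the higher and lower members were 8 and 3 for antimicrobial, 8 and 8 for oxidative stress and 4 and 2 for enteroendocrine genes. They were 5 and 1 for enterocyte, 2 and 1 for germline, 1 and 1 for fat body and 0 and 0 for regional genes. The remaining lists kept the counts given over all genes. Median, mean and test differed in sign for the oxidative stress (-0.18, 0.03, down), regional (0.09, 0.04, down), tracheal (0.32, -0.02, up), germline (-0.05, -0.04, up), ribosome biogenesis (0.04, 0.03, down) and lipid (-0.08, 0.13, up) lists. Of the genes in this paragraph, Drsl3, Cyp6a2, Ldh and AcCoAS kept their call in all 7 refits that left out 1 library. The others were called in 0 (Esp) to 6, with highest adjusted p from 0.055 to 0.27, without control library 1 for mesh and without 1 of the libraries labelled Shn-RNAi puc for the rest. The calls of kibra (adjusted p = 0.054), sd (0.14), Esp (0.053) and Rel (0.086) were lost with the length trend taken out.

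Of the 107 called genes named for this comparison, 60, 89 and 74 kept their call without control library 1, 2 and 3, 102 and 103 without Shn-RNAi library 1 and 2, and 52 and 40 without Shn-RNAi puc library 1 and 2. In every refit 38 kept it. Krn (0.52), spi (0.60), Dad (0.48), stg (0.68), pros (0.73) and Tk (0.45) did not pass, with edgeR adjusted p from 0.051 to 0.55.

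Both genotypes were set against the same 3 control libraries, and 427 genes were higher and 255 lower in both, 682 in all. Independent calls would give 48.2 and 20.2, and simulations with unchanged groups and shared controls gave 0.05 and 0.075 on average. No gene was changed in those simulations, so few were called at all, and they set no chance level for this overlap. The log2 changes of the 9076 genes correlated at 0.782 across genes, which are not independent replicates, against 0.392 from shared controls alone in the simulations. The count of 682 was 217 without control library 1, 286 without control library 3, 399 without Shn-RNAi library 2, 217 without Shn-RNAi puc library 1 and 136 without Shn-RNAi puc library 2. Only 4 genes were called in opposite directions by edgeR, chosen for naming after their values were seen. The lysozyme LysX (1.56 and -1.34), the mucin-like gene Muc14A (1.81 and -3.05) and CG34451 (0.68 and -0.60) were higher in the libraries labelled Shn-RNAi and lower in those labelled Shn-RNAi puc. CG7720 (-1.85 and 2.74) did the reverse.

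**Figure D3:**
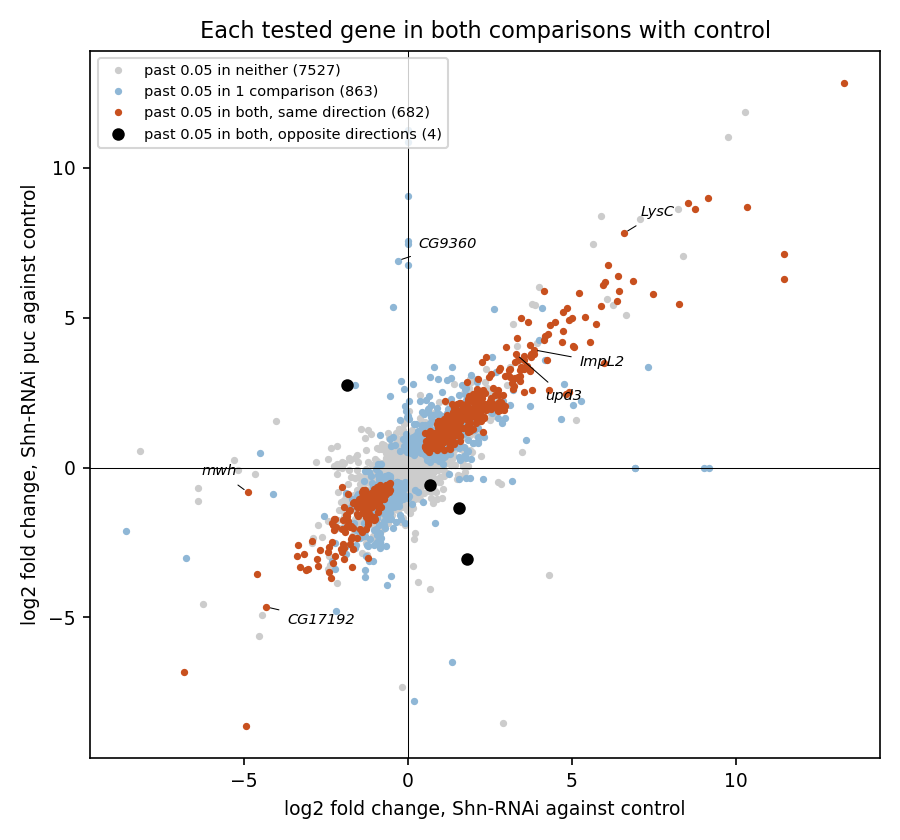
Fitted log2 fold change against control of each tested gene in the libraries labelled Shn-RNAi (horizontal) and Shn-RNAi puc (vertical), coloured by the comparisons that called it. Of the genes called in both, 682 share a direction and 4 do not. Values of genes with 0 counts in a group depend on the fit and are no measured folds.

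With edgeR, 0 genes were called in the same direction at both steps from control to Shn-RNAi to Shn-RNAi puc (at unadjusted p under 0.05, 34 stepped up, 38 down and 158 in opposite directions). DESeq2 gave 10 such genes, limma-voom 0, upper-quartile scaling in edgeR 1, and edgeR with the length trend taken out 4. At the last step the test recovered 23% of simulated 2-fold and 89% of simulated 4-fold changes, against 30% and 78% at the first. Most simulated 2-fold changes were thus missed at both steps, and whether this explains the absence of step genes was not tested. At both steps 6 genes were called in opposite directions: LysX, Muc14A, CG34451, CG7720, mwh and Ugt86Dd. Both steps share the libraries labelled Shn-RNAi, which favours opposite steps. The simulations gave 0.075 on average, but with no gene changed at either step, so they set no chance level for genes that change at the first.

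The third comparison asked what the mutant copy of puc added to Shn-RNAi. The libraries labelled Shn-RNAi puc (n = 2) and Shn-RNAi (n = 2) differed in 13 of 9076 genes, 8 higher and 5 lower in the former (edgeR adjusted p under 0.05; 579 at unadjusted p under 0.05). The clearest were CG9360, at 160 ± 77.8 against 1.12 ± 0.797 CPM, CG7720, at 400 ± 31.6 against 16.6 ± 3.73 CPM, and mwh, at 35.9 ± 8.4 against 2.12 ± 0.407 CPM. These 3 were also the genes that every refit with 1 library left out called. The signalling ligands upd3, upd2 and vn did not pass: upd3 had a log2 difference of 0.47 (SE 0.31, edgeR adjusted p = 0.88), upd2 of 1.01 (SE 0.62, adjusted p = 0.87) and vn of 0.00 (SE 0.31, adjusted p = 1).

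Among the 8 higher genes, CG32581 (20.2 ± 2.39 CPM, edgeR adjusted p = 0.0086) and CG42704 (15.2 ± 5.08 CPM, adjusted p = 0.03) had 0 counts in every control library and every library labelled Shn-RNAi, and were at least 211-fold and 161-fold higher than 3 counts over the latter group allow. CG9360 (log2 7.20, SE 0.54, adjusted p = 0.0022) and CG11893 (60.6 ± 27.6 against 1.09 ± 0.117 CPM, 5.79, SE 0.43, adjusted p = 0.0022) stood near 1 CPM in control too (1.34 and 1.52 CPM). CG7720 (4.59, SE 0.24, adjusted p = 0.00046) and mwh (4.06, SE 0.25, adjusted p = 0.00095) stood at 59.7 and 63.3 CPM in control, so mwh in the libraries labelled Shn-RNAi puc lay nearer to control. CG31436 (1.51, SE 0.16, adjusted p = 0.016) and the UDP-glycosyltransferase Ugt86Dd (1.34, SE 0.17, adjusted p = 0.033) were the others. Among the 5 lower genes, Burs, a subunit of the neurohormone bursicon, fell from 9.47 ± 6.74 to 0.0353 ± 0.05 CPM, a ratio of 0.00383 (counting interval 9.67e-05 to 0.0215; edgeR adjusted p = 0.03). Muc14A (30.8 ± 12.4 to 1.06 ± 0.398 CPM, -4.86, SE 0.40, adjusted p = 0.0033), LysX (417 ± 89.4 to 55.7 ± 16.3 CPM, -2.90, SE 0.31, adjusted p = 0.016), CG34451 (-1.28, SE 0.16, adjusted p = 0.033) and CG7912 (-1.20, SE 0.15, adjusted p = 0.035) were the others. LysX (3L 1194739 to 1195302) and mwh (3L 1200786 to 1232700) are close neighbours, and they moved in opposite directions. CG11893 (3R 25289889 to 25291366) and CG31436 (3R 25304137 to 25305651) are neighbours too, and both were higher.

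The counts of 8 higher and 5 lower became 6 and 3 without control library 1, 4 and 9 without Shn-RNAi library 1, 5 and 2 without Shn-RNAi library 2, and 4 and 0 without either library labelled Shn-RNAi puc. The refits called CG32581, CG11893 and Muc14A in 5 of 7, LysX in 4, Burs and CG42704 in 3, CG31436 in 1, and Ugt86Dd, CG34451 and CG7912 in 0. The highest adjusted p, 0.24 to 0.47, came without a library labelled Shn-RNAi puc, except for CG11893 (0.058, without Shn-RNAi library 2). The log2 difference of CG9360 was 6.56 without Shn-RNAi library 1, 8.13 without library 2 and 6.59 without Shn-RNAi puc library 1. The fitted log2 difference of Burs, which rests on 1 count in the libraries labelled Shn-RNAi puc, went from -7.80 to -8.39 and -6.81 without Shn-RNAi library 1 and 2, and to -6.91 and -10.17 without Shn-RNAi puc library 1 and 2. DESeq2 called 38 higher and 46 lower.

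**Figure D4:**
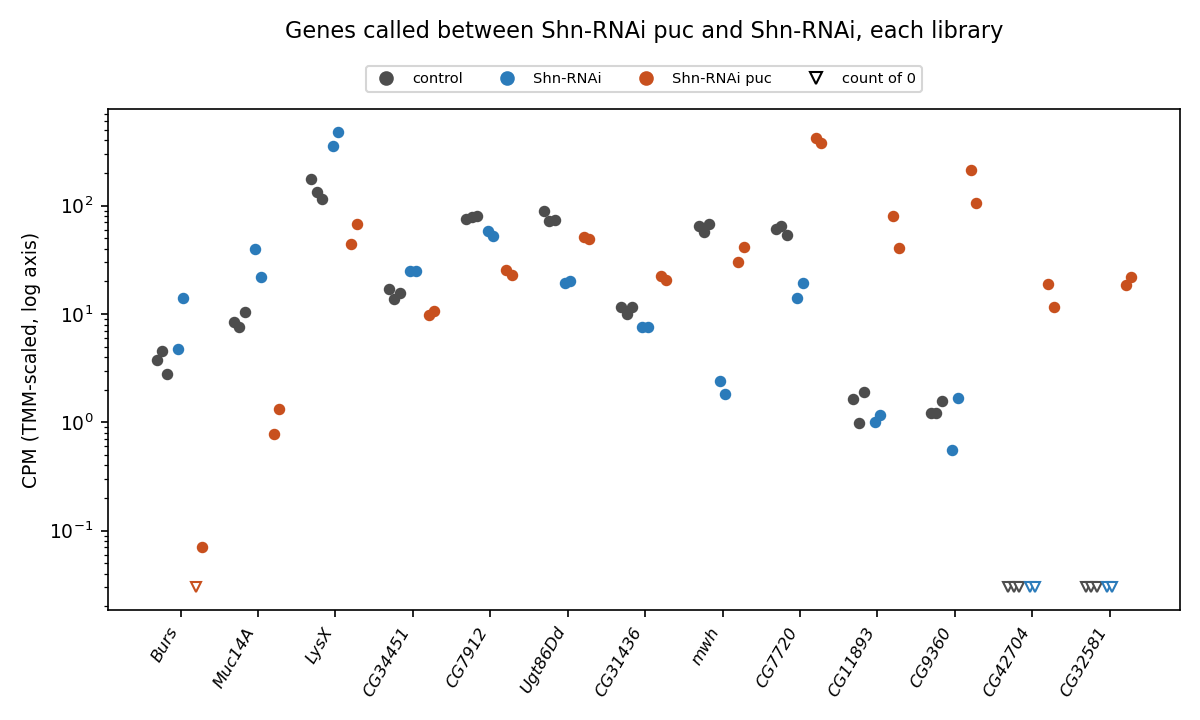
TMM-scaled CPM (log axis) of the 13 genes called between the libraries labelled Shn-RNAi puc and Shn-RNAi, 1 point per library, with open triangles at an arbitrary low level for counts of 0. CG42704 and CG32581 have counts only in the 2 libraries labelled Shn-RNAi puc.

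With a correlation estimated from the data none of the 32 lists was called in this comparison either (every adjusted p at least 0.93), and fry called 0. With the preset correlation camera called 4. Digestive enzymes were lower (median -0.53 over 53 genes, 1 called, LysX, and 3 adjusted over the list alone, camera adjusted p = 7e-08, adjusted p = 0.93 with an estimated correlation), with Jon25Bi at -1.62 (SE 0.29, edgeR adjusted p = 0.14) and tobi, an alpha-glucosidase, at -1.45 (SE 0.31, adjusted p = 0.21). Oxidative phosphorylation genes were lower (median -0.18 over 65 genes, 0 called by edgeR and 0 adjusted over the list alone, camera adjusted p = 0.019, adjusted p = 0.93 with an estimated correlation; 0.15 with the length trend taken out). Hemocyte markers were higher (median 0.39 over 10 genes, 0 called by edgeR and 1 adjusted over the list alone, camera adjusted p = 0.0078, adjusted p = 0.93 with an estimated correlation), with Hml at 2.71 (SE 0.45, edgeR adjusted p = 0.11). V-ATPase subunits were higher (median 0.18 over 20 genes, 0 called by edgeR and 0 adjusted over the list alone, camera adjusted p = 0.029, adjusted p = 0.93 with an estimated correlation). Without Shn-RNAi library 2 none of the 4 was called (adjusted p = 0.24 for digestive enzymes, 0.43 for hemocyte markers, 0.93 for oxidative phosphorylation and 0.71 for V-ATPase). Hemocyte markers and oxidative phosphorylation were also lost without Shn-RNAi puc library 2, where the latter turned upward (adjusted p = 0.41). V-ATPase was also lost without Shn-RNAi puc library 1. The number of lists called was 7 without Shn-RNAi library 1 and 9 without Shn-RNAi puc library 2.

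The other 28 lists were not called here (camera adjusted p from 0.052 to 0.99), and none of their genes passed with edgeR over all genes. They include the JNK list, the pathway that puc restrains (median 0.05 over 19 genes, mean 0.10, camera adjusted p = 0.51), with Jra at 0.37 (SE 0.17), egr at 0.24 (SE 0.14), rpr at 1.14 (SE 0.71) and hep at -0.30 (SE 0.20), at edgeR adjusted p from 0.8 to 0.88. The JAK-STAT (median 0.05; 0.51), EGFR (0.09; 0.77), matrix (0.03; 0.47), cell cycle (-0.09; 0.47) and progenitor (-0.21; 0.15) lists were likewise not called. Visceral muscle (median -0.22, camera adjusted p = 0.052) and heat shock genes (-0.68; 0.055) came closest. With the length trend taken out the heat shock list was called lower (adjusted p = 0.032) and cytosolic ribosomal proteins higher (adjusted p = 0.0046), with the preset correlation; without that step both had an adjusted p of 0.93 with an estimated correlation. The libraries labelled Shn-RNAi were uneven in heat shock genes: Hsp70Aa stood at 68 CPM in Shn-RNAi library 1 and 617 CPM in library 2. Control was uneven too, with Hsp70Aa at 11, 134 and 25.2 CPM in libraries 1, 2 and 3. Adjusted over the list alone, 1 gene passed in each of the tubule (ry), germline (AGO3), muscle (TpnC47D), fat body (Lsp1gamma) and enterocyte (Smvt) lists. Median, mean and test did not share a sign for the tubule (-0.08, -0.05, up), BMP (-0.02, 0.03, up), enterocyte (0.08, -0.04, up), Hippo (0, -0.02, up) and regional (-0.06, 0, up) lists.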

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

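The tests on called genes of the X chromosome, the JNK list, visceral muscle, mitochondrially encoded genes and progenitor markers were chosen only after the result was seen. Those on transcript length rest on an alternative that was also added after the data were seen. The test on the share of chromosome 3 was chosen before its result was seen. Each bootstrap interval below resampled the genes of a list with the libraries fixed. Such an interval treats related genes as independent and leaves out the spread between libraries.

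Between the libraries labelled Shn-RNAi puc and Shn-RNAi, 13 genes differed in their response against the shared control, by an edgeR test of the difference itself, and each stands here for that reason. Higher in the libraries labelled Shn-RNAi puc were CG32581 (at least 211-fold), CG42704 (at least 161-fold), CG9360 (log2 difference 7.20), CG11893 (5.79), CG7720 (4.59), mwh (4.06), CG31436 (1.51) and Ugt86Dd (1.34). Lower were Burs (ratio 0.00383), Muc14A (-4.86), LysX (-2.90), CG34451 (-1.28) and CG7912 (-1.20).

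The first pattern is this set of 13 genes. All 13 kept an edgeR adjusted p under 0.05 with the length trend taken out. In this comparison the 4 length classes had median log2 differences from -0.1 to 0.06 only, while each of the 13 genes differed by 1.2 or more in size. Differences of that size could hardly lose their call this way, so the refit is a weak test. The small class medians themselves argue against the length trend alone. The puc allele lies on chromosome 3, and variants carried along with it could change nearby genes: 9 of the 13 genes (69.2%) lie there against 3984 of 9059 tested genes (44%), Fisher's exact p = 0.0918, two-sided, odds ratio 2.87 (95% interval 0.8 to 12.8), which leaves this open, and such variants cannot act in cis on the 4 genes on the X chromosome (Muc14A, CG9360, CG42704 and CG32581). A change in JNK output is open too, since the JNK list had a median log2 difference of 0.05 (95% bootstrap interval -0.08 to 0.23) over members that went both ways. Other differences in strain background, on the X chromosome too, were not tested and cannot be told apart from the puc allele, which is on the label of these libraries only.

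The second pattern is the lower level of nuclear oxidative phosphorylation genes in both genotypes, called as a list with the preset correlation and not with an estimated one (adjusted p = 0.51 and 0.46). Fry gave the list adjusted p of 0.052 and 0.036. The length trend as the whole cause is argued against by a list median of -0.67 in the libraries labelled Shn-RNAi and -0.76 in those labelled Shn-RNAi puc with the trend taken out. Less muscle in the dissected tissue as the whole cause is not settled. The muscle median lay above the oxidative phosphorylation median by 0.62 (95% bootstrap interval 0.32 to 0.73) and 0.48 (0.29 to 0.79). But TpnC47D (-1.27 and -2.05) and Act87E (-1.20 and -1.77) fell beyond the oxidative phosphorylation medians of -0.81 and -0.98. Of the 21 muscle genes 5 and 4 rose, Zasp52 (0.99 and 1.43) among them, so the list median alone does not decide this. Fewer mitochondrial transcripts of every kind are argued against by the mitochondrially encoded genes, whose median lay above the nuclear one by 0.92 (0.8 to 1.01) and 0.78 (0.72 to 0.92). A change in the mix of gut cells stays open as untested, and so do strain background and the genotype itself.

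The third pattern is the set of 8 signalling, matrix and cell cycle lists called higher in both genotypes by camera with its preset correlation, none of which was called with an estimated correlation (lowest adjusted p = 0.32 and 0.38). Fry called all of them but the cell cycle list (adjusted p = 0.057) in the first comparison. In the second it left out the cell cycle (0.09) and Wingless (0.053) lists. With the preset correlation the length trend as the whole cause is argued against, since 7 of the 8 stayed called in both comparisons with it taken out, all but the Wingless list. A larger share of progenitor cells may raise such lists together, and then progenitor markers should rise at least as much as the 180 members of the lists. Their median minus that of the members was -0.08 (95% bootstrap interval -0.44 to 0.2) in the libraries labelled Shn-RNAi and -0.34 (-0.63 to 0.03) in those labelled Shn-RNAi puc, so neither reading is excluded. Of the 16 progenitor markers, 15 and 12 had positive log2 changes. The stem-cell gene esg hardly moved, at 13.6 to 18.9 CPM in control and 14.5 to 20.1 CPM in the other libraries. Strain background was not tested for this pattern. The RNAi label itself is unchecked by shn transcripts, as those of the whole midgut were not lower.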

How the results depend on the processing

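The length-trend alternative, the one without control library 2 and Shn-RNAi library 2, and the replicate block were chosen after seeing the data. The columns of the groups share replicate numbers, and the labels do not say that a number marks a shared batch or day, so the libraries share only a number. The difference of library 1 minus library 2 correlated over genes at -0.09 (control and Shn-RNAi), 0.11 (control and Shn-RNAi puc) and -0.1 (Shn-RNAi and Shn-RNAi puc). With the number as a replicate block, which leaves 2 residual degrees of freedom and takes up control library 3, 230 genes were higher and 91 lower in Shn-RNAi against control, 309 and 159 in Shn-RNAi puc against control, 7 and 4 in Shn-RNAi puc against Shn-RNAi, and 244 changed the same way in both genotypes. A group left with 1 library is assumed to vary like the other groups. Of 3776 values of the 210 called results for named genes under the alternatives, 3180 kept direction and call, 596 kept the direction and lost the call, and 0 turned. Of 360 values of called lists, 292 kept the call, 67 lost it and 1 turned: List Oxidative phosphorylation, Shn-RNAi puc against Shn-RNAi, without Shn-RNAi puc replicate 2 (camera adjusted p = 0.41, with 7.8e-12 to 0.93 over the refits that left out 1 library). With 1 library left out, genes higher in Shn-RNAi against control ran from 221 to 534 and lower from 64 to 301. They ran from 139 to 1033 and 33 to 839 in Shn-RNAi puc against control, and from 4 to 7 and 0 to 9 in Shn-RNAi puc against Shn-RNAi. Genes changed the same way in both genotypes ran from 136 to 629, and lists called in the third comparison from 5 to 9. These refits have fewer samples. DESeq2 gave 595 lower genes in Shn-RNAi against control, 38 higher and 46 lower in Shn-RNAi puc against Shn-RNAi, and 10 genes that step the same way from control to Shn-RNAi to Shn-RNAi puc. Upper-quartile scaling gave 1 such gene. A fit of only the 2 groups compared gave 1194 higher and 1012 lower in Shn-RNAi puc against control. With the length trend taken out there were 493 lower in Shn-RNAi against control, 18 higher and 11 lower in Shn-RNAi puc against Shn-RNAi, and 4 step genes. Without control library 2 and Shn-RNAi library 2 there were 909 higher and 587 lower in Shn-RNAi against control, 1038 lower in Shn-RNAi puc against control, 15 higher and 12 lower between the RNAi groups, 1024 changed the same way in both genotypes, and 2 step genes. A least fold change of 2 left 156 lower in Shn-RNAi against control, 474 higher and 296 lower in Shn-RNAi puc against control, and 403 changed the same way, by its construction. With an estimated correlation 0, 0 and 0 lists were called in the 3 comparisons, and fry called 10, 9 and 0. Apart from the least fold change and the left-out libraries, the cause was not tested. Of the 873, 1362 and 13 calls, DESeq2 kept 839, 1260 and 13 and limma-voom 823, 1298 and 12. No scaling moved the median of all genes by more than 0.047 in size (-0.047, upper-quartile, Shn-RNAi puc against control). Genes with few counts limit the falls and rises that could be seen: a group at 0 gives only the bounds printed with those genes.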

Other observations

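The gene families here were chosen after their values were seen, so no test of a family as a set is given. Lysozyme transcripts, of antibacterial and digestive enzymes, rose in both genotypes: 6 of 7 genes were higher in the libraries labelled Shn-RNAi, and 5 were higher and 1 lower in those labelled Shn-RNAi puc. Their summed level was 509 ± 68 CPM in control (SD, n = 3), 22600 ± 18400 CPM in the libraries labelled Shn-RNAi (n = 2) and 15800 ± 11.5 CPM in those labelled Shn-RNAi puc (n = 2). The libraries labelled Shn-RNAi held 9560 and 35600 CPM, so the order of the 2 genotypes is not settled, and the highest control library held 586 CPM. Turandot stress peptides summed to 1 ± 0.668, 697 ± 659 and 45.4 ± 5.3 CPM in the same order, with 4 and 3 of 4 genes higher. The mean of 697 rests on library 2 (1160 CPM, against 231 CPM in library 1).

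Jonah proteases, a family of digestive serine proteases, took 183000 ± 24200 CPM in control, 115000 ± 29500 CPM in the libraries labelled Shn-RNAi and 76900 ± 14200 CPM in those labelled Shn-RNAi puc. Of 16 genes, 4 were lower and 1 higher in the first genotype and 10 lower and 0 higher in the second (edgeR). Of 71 cytochrome P450 genes, 12 were higher and 5 lower in the first genotype, and 21 higher and 6 lower in the second, while their summed level was 5330 ± 265 CPM in control, 4440 ± 214 and 5120 ± 1430 CPM. The 13 mitochondrially encoded genes, with 0 called by edgeR, summed to 25400, 27300 and 25000 CPM.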
